A study of Solanum lycopersicum with 4 samples.

How the data were processed

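Degradome libraries were made from whole fruits of the tomato (Solanum lycopersicum) variety Ailsa Craig at 4 stages, with 1 library per stage: 5 days after pollination, mature green, breaker (the onset of colour change) and 7 days after breaker. The labels give the last stage as 7 days after breaker, while the file headers call it red ripe. The columns were assigned to it through the abbreviation that the sample's title and the headers share. Per the labels' protocols, polyadenylated RNA was purified with oligo-dT beads and carried through the PARE (parallel analysis of RNA ends) procedure. PARE captures the 5′ ends of uncapped, polyadenylated RNA fragments, and the enzyme MmeI then releases a short tag at that end. A tag therefore marks a place where an RNA was cut or was being degraded. CASAVA 1.8.0, Illumina's software for handling raw sequencing output, is named in the submitters' processing notes. The aligner, its settings and the filters on tags are not given in the sources used here.

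The deposited values came in 3 tables, which per the file headers hold CleaveLand output for ITAG2.3 cDNAs, the gene models of a tomato annotation release. Each table lists peaks opposite 1 position of the small RNA: 9, 10 or 11. Slicing of a plant mRNA by a microRNA is known to leave its 5′ end opposite position 10. The tag values are scores in tags per 10000000 tags (TP10M), per the file headers: 1 for the peak position and 1 for the whole cDNA in each library. They hold whole numbers only, with 0 at listed peaks, so they are a normalized unit rounded by the authors and not raw reads. A dash stands where no peak was listed. Per the file headers, each listed peak has a category from 0 to 4. The headers do not define them. In CleaveLand, category 0 is known to mark the single highest position of the cDNA and category 1 a shared highest position, categories 2 and 3 lower peaks, and category 4 a position with a single read. The deposited p-values are CleaveLand's likelihood of a chance peak and the q-values their Benjamini-Hochberg correction, per the file headers. A q-value was given only at peaks of category 0 or 1. The deposited alignment penalty score comes from TargetFinder, per the column name, with lower scores for better matches.

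Library totals were not given in the sources used here. Each peak of category 4 was listed at 0 TP10M and no other peak was, in each library. If category 4 is a single read, 1 read was worth less than 1 TP10M and each library held more tags than the unit is scaled to. The depth behind each value is otherwise unknown, and no counting interval was computed for TP10M values. The design fixed before the data were examined had foreseen exact counting intervals for counts. With a rounded score in place of counts, values and ratios are given without intervals.

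Filler entries with no values were dropped, which left 12952 entries and 12619 distinct sites (a cDNA and a position on it) on 5373 cDNAs, under 50 small RNA names. Each distinct site was counted once. A gene's value in a library was the sum over its distinct sites in the 3 tables under any small RNA name, with a dash adding nothing. Ratios were computed as log2 of the value plus a pseudocount of 1 TP10M, which understates differences of low values. A gene was called higher or lower when the values of both libraries summed to at least 50 TP10M and differed by at least 2-fold on that scale. With 1 library per stage these calls have no replicate check and no p-value, and they compare libraries. Values were used as deposited. Median-of-ratios size factors over 1021 cDNAs with totals of at least 10 TP10M in each library served as an alternative. Shares of sites have exact Clopper-Pearson 95% intervals, which cover counting error over sites only.

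Target classes were lists of genes that had both a given small RNA name and the annotation word of its known target class, such as miR172 with AP2-like. Most words came from a list fixed before the data were examined, which was meant for tables without small RNA names. Several were then adapted to the annotation's wording (such as MYB, AP2-like, NAC domain and resistance protein), and the demand for name and word together was set after the tables had been seen. 142 genes were in at least 1 class. The fixed list had 38 small RNA names, of which miR477, miR827, miR2118 and miR4376 had no entries in the tables. Families with at least 5 measured members (5 TP10M or more in either library) have a median log2 ratio. Its percentile is given among 10000 random lists of the same size, drawn from 5 bins of mean level. The minimum of 5 members was raised from 3 after medians of smaller lists had been computed. The pseudocount, and the reading of a dash as 0, were also set after the tables had been seen.

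The genes named in the text follow a rule fixed before the data were examined. It takes the gene with the most tags under each small RNA family, if at least 10 TP10M, the 5 largest differences in each direction per stage comparison among genes with at least 50 TP10M, and the 10 genes with the most tags. It also takes CNR, AP2a, Goblet, Lanceolate, AGO1 and DCL1 whatever their values. The rule's demand that a 95% interval exclude 1 could not be applied. Class members outside the rule, such as Solyc05g015510, Solyc04g049800, Solyc08g005430, Solyc09g007810 and Solyc01g087240, were chosen after their values were seen, as were the genes named only in the closing section. Gene identities and annotations are those of the tables, and positions are on the ITAG2.3 cDNA. Of the 5373 identifiers 0 were found in the reference table of gene names (assembly SLM_r2.1), so chromosome coordinates were not used here.

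Alternatives fixed before the data were examined were site minimums of 1 and 10 TP10M, the size factors, each entry counted, a penalty of at most 4, sums of at least 10 and 100 TP10M, and each table alone. Alternatives added later were sites of category 0 or 1, genes with identical values counted once, only sites under a family's own small RNA names with identical values counted once, a pseudocount of 5 TP10M, members above 0 in both libraries, the position 10 table alone for family medians, all genes under a small RNA name, and the position 11 table left out, alone or together with the choice of category 0 or 1 sites. The calling of genes was tested on simulated data for 5373 genes with a planted 4-fold difference. It recovered 42 of 42 planted genes that reached the sum minimum for mature green against 5 days after pollination, and 36 of 36 for breaker against mature green. It recovered 35 of 36 for 7 days after breaker against breaker and 39 of 39 for 7 days after breaker against 5 days after pollination, with 0 unchanged genes called in each. The simulated noise was Poisson only, with TP10M treated as counts and no spread between libraries. The simulation therefore checks that the calling rule works as written, and cannot give the rate of false calls in the real libraries. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.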

Results

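Whole tomato fruits were profiled by degradome sequencing at 4 stages, with 1 library each, to find which mRNAs carried the cut ends that microRNAs leave. The 5 days after pollination library had 7215 distinct sites listed, mature green had 6460, breaker had 3328 and 7 days after breaker had 5922. Sites with at least 5 TP10M numbered 373, 351, 274 and 357 in the same order, and carried 7601, 8878, 11353 and 7755 TP10M. A single site, the miR172 site of AP2a (Solyc03g044300), held 25.6% of all listed TP10M in the breaker library. The most abundant site held 4.39% at 5 days after pollination (growth-regulating factor 3, Solyc08g075950), 6.87% at mature green and 10.1% at 7 days after breaker (both in Solyc04g071610, annotated as water-stress inducible protein 3). Most predictions were weak matches: 11656 of 12952 entries had a penalty of 5 or more, and 2833 were under the single name miR414.

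Cut ends that stood out on their cDNA lay mainly opposite position 10, where microRNA slicing is known to occur. Among distinct sites of category 0 or 1, position 10 held 72 of 81 at 5 days after pollination, 85 of 98 at mature green, 38 of 53 at breaker and 51 of 79 at 7 days after breaker. These are shares of 88.9% (95% exact interval 79.95 to 94.8), 86.7% (78.4 to 92.7), 71.7% (57.7 to 83.2) and 64.6% (53.0 to 75.0). They carried 98.2%, 94.8%, 97.6% and 87.9% of the TP10M at such sites. Gene copies with identical values, such as Solyc02g064960 and Solyc02g093150, were counted as separate sites, which the intervals do not allow for. Among all sites of at least 5 TP10M the share at position 10 was lower, at 46.5%, 46.2%, 38.3% and 41.1%. The authors' deposited table for position 10 had q-values of at most 0.05 at 59, 63, 34 and 46 entries. The position 11 table had 0 peaks of category 0 or 1 in the libraries of 5 days after pollination and mature green, against 8 at breaker and 5 at 7 days after breaker. Whether such peaks were removed before deposit is not given in the sources used here, so the shares over 3 positions do not compare the stages. Without that table the share among category 0 or 1 sites was 88.9%, 86.7%, 84.4% (95% exact interval 70.5 to 93.5) and 68.9% (57.1 to 79.2) in stage order. Among sites of at least 5 TP10M it was then 61.5%, 60.8%, 56.4% and 54.0%.

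**Figure D1:**
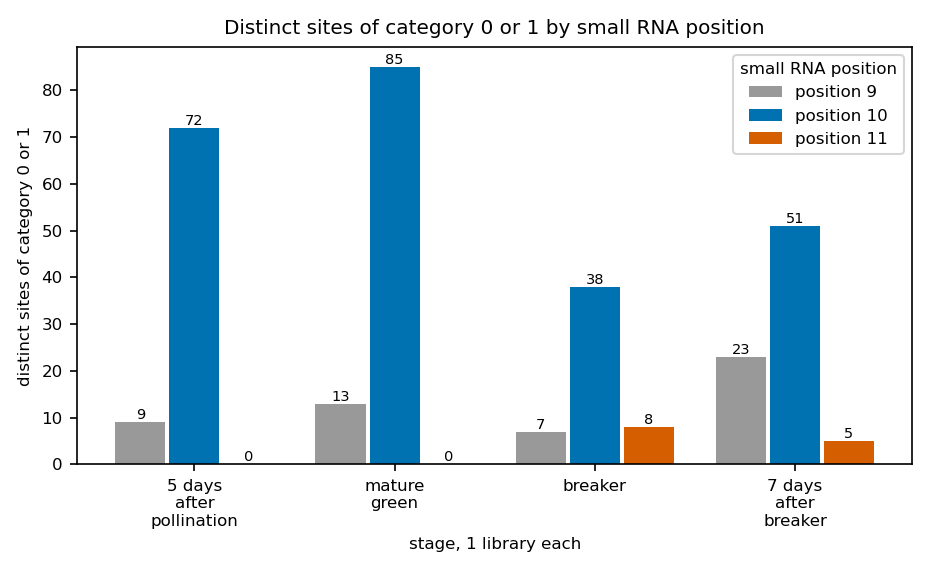
Number of distinct sites of category 0 or 1 (y axis) in each stage's library (x axis), with bars for small RNA positions 9, 10 and 11. Position 10 is the tallest bar at each stage, from 38 sites at breaker to 85 at mature green, and position 11 has 0 sites at 5 days after pollination and mature green.

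Genes of the known microRNA target classes were frequent among the position 10 sites that stood out. Of 132 cDNAs with a category 0 or 1 site at position 10 in at least 1 library, 66 were class genes (50%), against 3.37% of all cDNAs listed at position 10. Gene copies with identical values were counted separately in these numbers. 15 cDNAs had a position 10 site of category 0 in all 4 libraries, and all 15 were class genes. They were 4 AP2-like genes under miR172, 4 growth-regulating factors under miR396, 2 auxin response factors under miR160, 2 GRAS genes under miR171, and 1 each for miR156 and miR157 (CNR), miR169 (an NF-YA subunit) and miR403 (annotated as ARGONAUTE 1). The AP2-like genes Solyc02g064960 and Solyc02g093150 among them had identical values and are not independent.

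By family, all 8 AP2-like genes under miR172 and all 8 growth-regulating factors under miR396 had a site of category 0 or 1 at position 10 in at least 1 library. So did 6 of 9 SBP-box genes under miR156 and miR157, 3 of 5 auxin response factors under miR160, 4 of 4 NAC genes under miR164, and 2 of 6 class III homeodomain-leucine zipper genes under miR165 and miR166. The count was 4 of 5 NF-YA genes under miR169, 3 of 4 GRAS genes under miR171, 3 of 3 F-box genes under miR393, and 3 of 15 MYB or TCP genes under miR159 and miR319. The single members under miR168 (AGO1), miR394 (F-box) and miR403 also had one, as did 1 of 3 superoxide dismutases under miR398. Among NBS-LRR disease resistance genes, 6 of 31 under miR482 and 12 of 29 under miR6022 to miR6027 had one, and these lists share 12 genes. The count was 0 for the class genes of miR162 (1 gene), miR167 (3), miR390 and TAS3 (1), miR395 (2), miR397 (4), miR828 (1), miR858 (9) and miR5300 (2). Some class genes had no entry at position 10 and could not be counted. Those listed there numbered 2 for miR167, 0 for miR397, 2 for miR858 and 1 for miR5300. They numbered 28 for miR482, 25 for miR6022 to miR6027, and 14 for miR159 and miR319. For miR399 and miR408 the classes had 0 listed genes, and no class was fixed for miR1919.

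The gene with the most tags under a small RNA name was often outside its class. This held for 14 of the 24 families that had at least 1 listed class gene, and 0 of those 14 genes had a category 0 or 1 site at position 10. The largest was Solyc04g071610 under miR156 and miR157, at an alignment penalty of 7, whose tags were spread over positions 9, 10 and 11 with 1200, 659 and 514 TP10M at 7 days after breaker. All 3 were peaks of category 2. The type 2 metallothionein Solyc09g010800, under miR398 at a penalty of 5, had 256, 30 and 97 TP10M at positions 10, 9 and 11 in mature green. By contrast AP2a had 3353 TP10M at position 10 (cDNA position 1384) and 40 at position 9 in the breaker library.

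**Figure D2:**
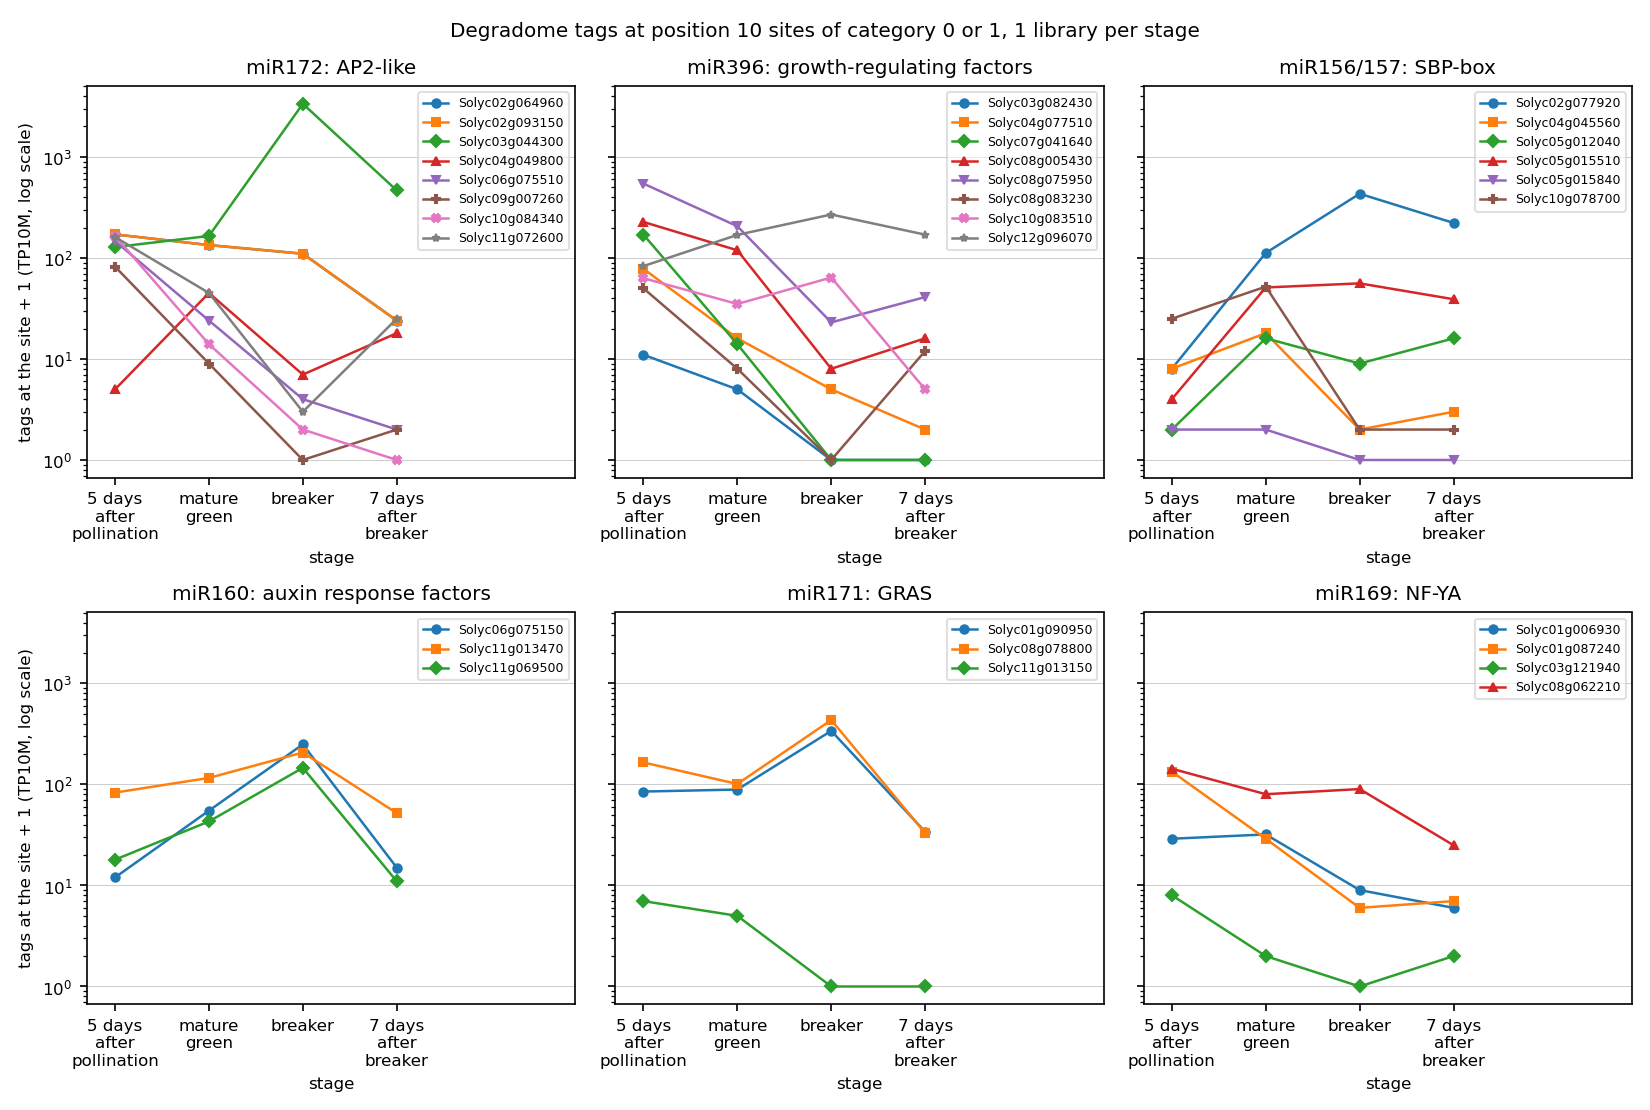
Tags at position 10 sites of category 0 or 1 (y axis, TP10M plus 1, log scale) by stage (x axis) for the class genes of 6 small RNA families, 1 library per stage, with unlisted peaks drawn as 0. AP2a (Solyc03g044300) reaches 3353 TP10M at breaker, and the lines of Solyc02g064960 and Solyc02g093150 coincide.

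Target sites of the known classes were most often highest in young fruit. Of 67 class genes with a position 10 site of at least 5 TP10M in a library, 37 had their highest value at 5 days after pollination, 17 at mature green, 13 at breaker and 0 at 7 days after breaker. This count was made after the values had been seen. After median-of-ratios scaling the numbers were 37, 12, 16 and 0 of 65 genes. Some of these genes had identical values in all 4 libraries, such as the class III homeodomain-leucine zipper genes Solyc03g120910, Solyc08g066500 and Solyc12g044410 (63, 142, 119 and 20 TP10M) and the AP2-like pair Solyc02g064960 and Solyc02g093150 (170, 133, 109 and 23). The NBS-LRR genes Solyc04g009120, Solyc04g009150, Solyc04g009660 and Solyc04g026110 shared 27, 7, 0 and 0 TP10M at a miR6027 site. Such copies do not count as independent members of a list. With identical genes counted once the numbers were 31, 14, 13 and 0 of 58. Families differed: 6 of 8 AP2-like genes and 6 of 8 growth-regulating factors were highest at 5 days after pollination. For SBP-box genes it was 0 of 7, and for miR160 targets 0 of 4, with all 4 highest at breaker. No such count was made for sites outside the classes.

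From 5 days after pollination to mature green, cut ends of CNR (Solyc02g077920), a ripening regulator of the SBP-box family, went from 7 to 119 TP10M (log2 ratio 3.91). Another SBP-box gene, Solyc05g015510, went from 5 to 58 (3.30). Of the 7 measured SBP-box genes, Solyc03g114850 and Solyc12g038520 shared their position 10 values (2, 8, 0 and 2 TP10M in stage order). Counting them separately, 5 of the 7 were at least 2-fold higher with 0 lower. Growth-regulating factors, which promote cell proliferation in young organs, went the other way: 5 of 8 were lower and 1 higher. Growth-regulating factor 1 (Solyc07g041640) went from 170 to 14 (-3.51) and growth-regulating factor 3 (Solyc08g075950) from 547 to 208 (-1.39), while growth-regulating factor 5 (Solyc12g096070) had 84 at 5 days after pollination and was higher at mature green (1.03). Of 8 AP2-like genes 4 were lower, such as Solyc10g084340 (-3.50, with 14 at mature green), and 1 was higher, Solyc04g049800 (4 to 46, 3.23).

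The AGO1 gene Solyc06g072300, the argonaute that loads most microRNAs, had 225 TP10M at 5 days after pollination and 101 at mature green (-1.15), and the miR403 target Solyc02g069260 had 684 at mature green (2.10). The miR164 target Solyc07g066330, a NAC gene, went from 79 to 1 (-5.32). Growth-regulating factor 12 (Solyc08g079800), listed under miR5303, went from 46 to 4 (-3.23), and Solyc07g043000, of unknown function, had 51 and was not listed at mature green. The 5 largest differences upward were in cDNAs with no category 0 or 1 site. Solyc04g071610 went from 5 to 1609 (8.07) and the agglutinin gene Solyc03g116230 from 10 to 277 (4.66). A 2S albumin (Solyc08g080490, 152 TP10M), a legumin (Solyc09g072560, 93) and an oleosin (Solyc12g010920, 79), all abundant proteins of seeds, were not listed at 5 days after pollination.

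In all, 81 genes reached 50 TP10M in this pair of libraries, of which 25 were at least 2-fold higher at mature green, 21 lower and 35 between. Among the 34 class genes 9 were higher and 11 lower, with genes of shared site values counted separately here and below. The family median was 1.65 for SBP-box genes (percentile 99.2 among random lists), -1.10 for AP2-like genes (4.76) and -1.26 for growth-regulating factors (2.46). The SBP-box percentile treats Solyc03g114850 and Solyc12g038520 as independent members, although they shared their position 10 values. With sites under miR172 alone and identical values counted once, the AP2-like median was -1.84 (0.57). The class III homeodomain-leucine zipper median was 0.87, without a percentile here and below, since 3 of its 5 members share their site values. For NBS-LRR genes, sites under a family's own names with identical values counted once gave 5 sets of values for miR6022 to miR6027, of which 2 were lower and 1 higher (median -0.58, percentile 25.9), and 4 for miR482, of which 3 were lower. With a sum of at least 10 TP10M the split was 92 higher and 117 lower, and among sites of category 0 or 1 it was 10 and 11.

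From mature green to breaker, AP2a, a known regulator of ripening, had 3401 TP10M at breaker, a log2 ratio of 4.35 over mature green and the largest difference upward. CNR went from 119 to 451 (1.91). The 4 auxin response factors under miR160 that reached 50 TP10M had higher values, 3 of them by at least 2-fold: Solyc06g075150 went from 55 to 249 (2.16), Solyc11g069500 from 45 to 154 (1.75), Solyc09g007810 from 13 to 38 (1.48) and Solyc11g013470 from 116 to 207 (0.83). Both abundant GRAS genes under miR171 were higher, Solyc08g078800 (100 to 437, 2.12) and Solyc01g090950 (89 to 340, 1.92). A gene annotated as a DNA cytosine methyltransferase, Solyc02g062740, with a category 0 site under miR396 at cDNA position 1161, went from 17 to 148 (3.05).

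Other class members were lower at breaker. At least 2-fold lower were 5 of 8 AP2-like genes, 5 of 7 growth-regulating factors and 5 of 7 SBP-box genes, counting genes with shared site values separately. The SBP-box gene Solyc10g078700 went from 55 to 1 (-4.81), growth-regulating factor 4 (Solyc08g005430) from 118 to 7 (-3.89) and growth-regulating factor 3 (Solyc08g075950) from 208 to 22 (-3.18). AGO1 went from 101 to 17 (-2.50) and the miR403 target Solyc02g069260 was lower than its 684 (-2.01). Of cDNAs with no category 0 or 1 site, the 2S albumin went from 152 to 1 (-6.26) and alpha-tubulin Solyc04g077020 from 63 to 3, while the legumin and the oleosin had 0 TP10M at breaker. The genes Solyc00g006050 (4 to 66, 3.74), Solyc02g080510 (6 to 60, 3.12) and Solyc12g062300 (8 to 71) were higher. Solyc00g006050 and Solyc12g062300 shared 1, 1, 15 and 4 TP10M in stage order at a miR414 site, so they are not fully independent.

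62 genes reached 50 TP10M, of which 19 were at least 2-fold higher at breaker, 25 lower and 18 between. Among 25 class genes 7 were higher and 7 lower, against 11 and 6 after median-of-ratios scaling. The family median was -3.25 for SBP-box genes (percentile 1.40), although CNR in that family was higher, and -2.70 for AP2-like genes (3.97), although AP2a was higher. With sites under miR172 alone and identical values counted once, the AP2-like median was -2.75 (5.48). It was -3.00 for growth-regulating factors (2.34), and -0.23 for class III homeodomain-leucine zipper genes, which turned to 0.19 after scaling. Of NBS-LRR genes at sites under their own small RNA names, all 4 distinct sets of values for miR6022 to miR6027 were lower, and 1 was measured for miR482. The breaker library listed the fewest sites. Scaling moves the log2 ratio of abundant genes in this pair by about 0.42 upward, and low values differ from that because of the pseudocount. The split was then 28 higher and 21 lower, or 57.1% higher among the called genes against 43.2% as deposited. With a pseudocount of 5 TP10M the medians of AP2-like, growth-regulating factor and SBP-box genes were -1.52, -1.26 and -1.49.

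From breaker to 7 days after breaker, none of the 19 class genes that reached 50 TP10M was at least 2-fold higher and 13 were lower, counting genes with shared site values separately. With the family minimum of 5 TP10M in either library, 2 of 5 AP2-like genes were higher and 3 lower on the same count. Of growth-regulating factors 2 of 5 were then higher and 1 lower. Among the miR160 targets, Solyc06g075150 went from 249 to 14 TP10M (-4.06), Solyc11g069500 from 154 to 10 (-3.82) and Solyc11g013470 from 207 to 51 (-2.0). The GRAS genes Solyc08g078800 (437 to 32, -3.73) and Solyc01g090950 (340 to 33, -3.33), growth-regulating factor 2 (Solyc10g083510, 64 to 4, -3.70) and AP2a (3401 to 478, -2.83) were lower too. CNR had 451 and 233 (-0.95), and the cytosine methyltransferase gene Solyc02g062740 had 148 and 14 (-3.31).

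The 5 largest differences upward were again in cDNAs with no category 0 or 1 site. They included 2 HSP90 genes, Solyc06g036290 (1 to 52, 4.73) and Solyc07g065840 (5 to 45, 2.94), which encode a chaperone. The major latex-like gene Solyc00g060810 went from 10 to 155 (3.83), vacuolar processing enzyme Solyc08g065610 from 9 to 92 (3.22) and the ubiquitin-conjugating enzyme Solyc02g087750 from 6 to 47 (2.78). A ubiquitin gene, Solyc10g006480, went from 63 to 3.

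60 genes reached 50 TP10M, of which 17 were higher at 7 days after breaker, 27 lower and 16 between. The family median was -2.49 for class III homeodomain-leucine zipper genes, of which 3 share their site values, and -2.20 for AP2-like genes, the latter -0.38 with identical genes counted once, over 4 genes and so without a percentile, and 1.46 with all genes listed under miR172. It was 0.83 over 5 growth-regulating factors (percentile 59.97), and -0.40 over 6 after median-of-ratios scaling, which brought 1 more gene to the minimum. That scaling moves the log2 ratio of abundant genes in this pair by about 0.48 downward. It gave 10 higher and 36 lower, or 21.7% higher among the called genes against 38.6%, with 0 higher and 17 lower among 20 class genes. With a sum of at least 10 TP10M the split turned to 146 higher and 71 lower, and among sites of category 0 or 1 it was 1 and 13.

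Between the first and the last stage, 22 of 28 class genes were lower at 7 days after breaker and 4 were higher, counting genes with shared site values separately. The 4 were CNR (7 to 233 TP10M, 4.87), the SBP-box gene Solyc05g015510 (5 to 49, 3.06), AP2a (129 to 478, 1.88) and growth-regulating factor 5 (84 at 5 days after pollination, 1.03). The other AP2-like genes and growth-regulating factors with 50 TP10M were lower: growth-regulating factor 3 (Solyc08g075950) went from 547 to 40 (-3.74), and the AP2-like genes Solyc06g075510 and Solyc09g007260 from 148 to 1 (-6.22) and from 83 to 1 (-5.39). Growth-regulating factor 1 (Solyc07g041640) had 170 at 5 days after pollination and was not listed at 7 days after breaker, and the AP2-like gene Solyc10g084340 had 0 at 7 days after breaker. AGO1 went from 225 to 22 (-3.30), NF-YA gene Solyc01g087240 from 135 to 8 (-3.92), and the miR164 target Solyc07g066330 from 79 to 5 (-3.74).

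Of cDNAs with no category 0 or 1 site, Solyc04g071610 had 5 and 2373 TP10M (8.63). The major latex-like gene Solyc00g060810 (155) and xyloglucan endotransglucosylase/hydrolase 14 (Solyc01g081060, 50), a cell wall enzyme, were not listed at 5 days after pollination, and vacuolar processing enzyme Solyc08g065610 (92) had 0 TP10M there. 68 genes reached 50 TP10M, of which 13 were higher, 36 lower and 19 between. With a sum of at least 10 TP10M the split was 106 higher and 141 lower. Family medians were -3.71 for growth-regulating factors (percentile 0.04), -2.85 for AP2-like genes (0.66, or 1.8 at miR172 sites with identical values counted once) and -1.58 for class III homeodomain-leucine zipper genes. Of NBS-LRR genes at sites under their own small RNA names, 3 of 3 distinct sets of values for miR6022 to miR6027 and 3 of 4 for miR482 were lower, too few for a percentile. The SBP-box median was 1.53 (96.9), with 3 of 6 genes higher and 2 lower, and -0.42 with a site minimum of 1 TP10M.

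Of the developmental genes fixed in advance, Goblet (Solyc07g062840, a miR164 target) had 3, 2 and 1 TP10M at 5 days after pollination, mature green and 7 days after breaker, and was not listed at breaker. Lanceolate (Solyc07g062680, a miR319 target) had 1 TP10M at 5 days after pollination and 0 or no listing in the other libraries. DCL1 (Solyc10g005130, annotated as a ribonuclease 3-like protein) had 2 and 3 TP10M at its miR162 site in the first 2 libraries and 0 in the others. The second AGO1 gene, Solyc03g098280, had no entry. Values this low give no difference between stages, as the depth behind them is unknown.

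For AP2a and CNR the tags on the rest of the cDNA also differed between stages. On the whole AP2a cDNA there were 267, 364, 5359 and 1582 TP10M at the 4 stages in order, of which the miR172 site held 47.6%, 45.1%, 62.6% and 29.4%. On the whole CNR cDNA there were 38, 829, 2549 and 1698 TP10M, and its miR156 and miR157 site at cDNA position 840 held 7, 111, 431 and 221. Some other targets did not follow this. The Solyc02g062740 site held 17 TP10M at mature green and 142 at breaker, of totals of 267 and 258. The miR403 site of Solyc02g069260 held 155 at 5 days after pollination and 679 at mature green, of totals of 2317 and 2258. In others the site and the cDNA total differed in the same direction. The miR396 site of Solyc04g077510 held 77 at 5 days after pollination and 15 at mature green, of totals of 613 and 67. The miR172 site of Solyc04g049800 held 4 and 44 in the same libraries, of totals of 11 and 76. A degradome library does not separate more slicing of an mRNA from more of that mRNA, and transcript levels were not measured in these libraries.

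**Figure D3:**
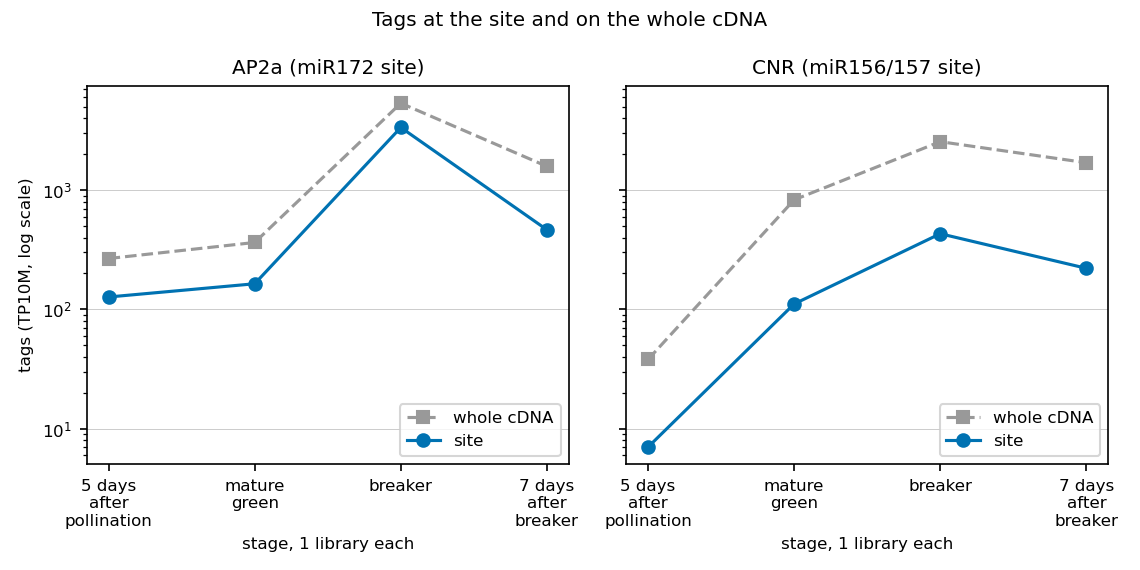
Tags at the position 10 site and on the whole cDNA (y axis, TP10M, log scale) by stage (x axis) for AP2a and CNR, 1 library per stage. Both lines of both genes are highest at breaker, with 3353 and 5359 TP10M for AP2a and 431 and 2549 for CNR.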

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

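The alternatives chosen only after the data had been seen were category 0 or 1 sites, the position 11 table left out, both of these together, identical genes counted once, a family's own sites with identical values counted once, members above 0 in both libraries, all genes under a small RNA name, the pseudocount of 5 TP10M, and the position 10 table alone for family medians. With 1 library per stage no spread between replicates exists, so medians, counts and tag sums were taken as unchanged within 1.5 times, a bound set after the tables were seen, and shares within their 95% interval. On that basis 33 stage counts, 14 tag sums, 11 shares and 8 site numbers were unchanged. In the same order 47, 6, 21 and 12 moved, so most stage counts, shares and site numbers depended on the setting. Of the family medians 53 moved beyond that bound and 5 changed sign, with that of growth-regulating factors after scaling counted under both. The class III homeodomain-leucine zipper median for breaker against mature green went from -0.23 to 0.19 after scaling, which is within the bound. The counts of class genes by highest stage stayed within the bound under each of the 3 alternatives tried for them. No paired analysis was possible because the labels carry no replicate numbers and each stage has 1 library. The 99% interval was not run, since the values are not counts. Unscaled values were not run, since the values are deposited scaled, and a penalty of at most 4 was used in place of the better-scoring part of the entries. The depth behind each value is unknown, which limits above all the genes near the minimum. For each result that moved or changed sign below, the cause was not tested.

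For the libraries of 5 days after pollination, mature green, breaker and 7 days after breaker in that order, a site minimum of 1 TP10M gave 3755, 3253, 1418 and 3181 sites, with 12355 TP10M in the first library and 11834 in the last. A minimum of 10 TP10M gave 163, 154, 120 and 133 sites. A penalty of at most 4 gave 65, 73, 64 and 52 sites with 4097, 3650, 7097 and 1916 TP10M. The share of sites at position 10 was 83.1%, 84.9%, 54.7% and 73.1% with that penalty, 88.9%, 86.7%, 71.7% and 64.6% among category 0 or 1 sites, and 61.5%, 60.8%, 56.4% and 54.0% without the position 11 table. Among category 0 or 1 sites without that table it was 88.9%, 86.7%, 84.4% and 68.9%. With a minimum of 1 TP10M it was 36.6%, 36.4% and 34.6% at 5 days after pollination, mature green and 7 days after breaker. With a minimum of 10 TP10M it was 56.8% at mature green and 51.5% at 7 days after breaker.

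Mature green against 5 days after pollination had 92 genes higher and 117 lower with a sum of at least 10 TP10M, and 11 and 9 with at least 100. It had 3 and 3 at position 9 alone, 15 higher at position 10 alone, 3 and 2 at position 11 alone, and 10 and 11 among category 0 or 1 sites. Breaker against mature green had 71 higher and 153 lower with a sum of at least 10, and 9 and 8 with at least 100. It had 0 and 4 at position 9 alone, 8 and 9 at position 10, 1 and 1 at position 11, and 7 and 7 among category 0 or 1 sites. In 7 days after breaker against breaker, 10 genes were higher after median-of-ratios scaling. A sum of at least 10 gave 146 higher and 71 lower, and at least 100 gave 6 and 14. It had 4 and 1 at position 9 alone, 2 and 15 at position 10, 2 and 1 at position 11, and 1 and 13 among category 0 or 1 sites. Last against first stage had 106 higher and 141 lower with a sum of at least 10, and 8 and 18 with at least 100. It had 4 and 2 at position 9 alone, 7 higher at position 10, 3 and 2 at position 11, and 4 and 21 among category 0 or 1 sites.

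Median log2 ratios of the families moved as follows, with SBP-box genes under miR156 and miR157. For them, mature green against 5 days after pollination gave 2.47 with a site minimum of 10 TP10M and 0.36 with all genes under the name. Breaker against mature green gave -1.42 with a minimum of 1, -2.33 with a minimum of 10, -2.33 with members above 0 in both libraries, -1.58 with all genes under the name and -1.49 with the pseudocount of 5. Last against first stage changed sign to -0.42 with a minimum of 1, and was 3.26 with a minimum of 10, 3.0 at position 10 alone and 0 with all genes under the name. The class III homeodomain-leucine zipper median was 0.015 for mature green against 5 days after pollination and -0.58 for 7 days after breaker against breaker with all genes under the name, the latter -1.90 with the pseudocount of 5.

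The AP2-like median was -1.84 for mature green against 5 days after pollination with identical genes counted once, also at own sites, and -1.52 for breaker against mature green with the pseudocount of 5. For 7 days after breaker against breaker it was -1.0 with a minimum of 1 and -0.38 with identical genes counted once, also at own sites, and changed sign to 1.46 with all genes under the name. Last against first stage was -0.78 with all genes under the name. The growth-regulating factor median was -0.061 for mature green against 5 days after pollination and -0.43 for last against first stage with all genes under the name. For breaker against mature green it was -1.68 with members above 0 in both libraries, -1.81 with all genes under the name and -1.26 with the pseudocount of 5. For 7 days after breaker against breaker it was 0.070 with a minimum of 1, 0.070 with members above 0 in both libraries and -0.40 after median-of-ratios scaling.

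In both NBS-LRR lists 4 genes share 1 set of values at a miR6027 site. With a family's own sites and identical values counted once, mature green against 5 days after pollination was -0.58 for miR6022 to miR6027, and last against first stage was -3.32 for them and -2.31 for miR482. Over all listed sites these were -1.74, -4.11 and -4.91. The NBS-LRR median of miR482 over all listed sites with a minimum of 1 was 0 for mature green against 5 days after pollination, -1.0 for breaker against mature green and -1.0 for last against first stage. Breaker against mature green was -2.58 with all genes under the name and -1.38 with the pseudocount of 5. Last against first stage was -3.15 with each entry counted, -1.81 with members above 0 in both libraries, -3.17 with identical genes counted once, -1.40 with all genes under the name and -2.77 with the pseudocount of 5. For miR6022 to miR6027, mature green against 5 days after pollination was 0 with a minimum of 1, -0.44 with identical genes counted once and -0.30 with all genes under the names. Breaker against mature green was -1.58 with a minimum of 1, -2.14 with members above 0 in both libraries, -1.64 with all genes under the names and -1.38 with the pseudocount of 5. Last against first stage was -1.32 with a minimum of 1, -4.91 with a minimum of 10, -3.32 with each entry counted, -4.86 with a penalty of at most 4 and -2.13 with the pseudocount of 5, and changed sign to 0.22 with all genes under the names.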

Other observations

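The gene lists by annotation word, and the tests for paralogs, for tags on the whole AP2a cDNA, for identical values and for the share of tags on these cDNAs, were chosen only after the results had been seen. Tags over whole cDNAs also differed between stages for genes that are not known microRNA targets. A cDNA without a listed peak in a library has no total there, so sums and counts of highest totals follow listing in part. Of 88 ribosomal protein genes, 54 were listed in all 4 libraries, with medians of 2953.5, 969, 881 and 1132.5 TP10M from the first stage to the last, and 48 of these were highest at 5 days after pollination. Of 18 tubulin genes 8 were listed in all 4, with medians of 5558.5, 2299, 686.5 and 648 TP10M and 5 highest at 5 days after pollination. Of 22 photosystem or chlorophyll genes 8 were listed in all 4, with medians of 2776, 2148, 517.5 and 852.5 TP10M and 5 highest at the same stage. For 13 histone genes and 36 cell wall hydrolases only 2 and 1 were listed in all 4, too few for a comparison. Genes of seed storage or oil body proteins were listed in different libraries, 3, 14, 8 and 16 of 20 in stage order and 0 in all 4. Among them the 2S albumin Solyc08g080490 had 91336 TP10M at mature green and 2424 at breaker, and was not listed at 5 days after pollination.

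Over the 20 of 72 heat shock genes listed in all 4 libraries, the medians were 587.5, 692, 439.5 and 1515.5 TP10M in stage order, while 9 of the 20 were highest at 5 days after pollination and 6 at 7 days after breaker. Of 4 genes with a carotene or carotenoid annotation 0 were listed in all 4. The zeta-carotene isomerase Solyc12g098710, an enzyme on the path to lycopene, had 214 TP10M at mature green, 3382 at breaker and 6862 at 7 days after breaker, and was not listed at 5 days after pollination. Vacuolar processing enzyme Solyc08g065610 had 700, 5662, 14804 and 33970 TP10M over its cDNA. The abscisic acid receptor gene PYL8 (Solyc01g095700) had the only site of category 0 in all 4 libraries at position 9, at cDNA position 916 under miR156 and miR157 with a penalty of 7. It had 23, 141, 64 and 136 TP10M, of cDNA totals of 251, 309, 126 and 226.

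The AP2a site had 20.4 times as many TP10M in the breaker library as in the mature green library. Scaling of the breaker library is argued against, as median-of-ratios scaling gave 27.4 times. Full sharing of its tags with a listed paralog is argued against too, with 0 sites of other genes having the same 4 values. Partial sharing, or sharing with a gene that is not listed, would give no such match and was not tested. More tags from the whole cDNA stay open: the rest of the AP2a cDNA had 10.03 times as many, so a higher mRNA level could account for part of the difference. Stage cannot be told apart from library here, and a biological difference between the stages stays untested.

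Sites of different genes had identical values in all 4 libraries in 22 groups of 36 genes, among 306 sites searched. A candidate explanation is that the same tags were assigned to every gene copy they match. Of 31 distinct gene pairs with identical values 77.4% shared their annotation, against 0.667% of random pairs of genes. The share was 84.1% of 44 pairs when a gene pair was counted at each of its sites. The test asked for over 80% of gene pairs, so this explanation stays open. Annotations counted as shared only when worded the same, which lowers the share. Solyc02g037530 (auxin response factor 8) and Solyc03g031970 (auxin response factor 8-1) thus counted as different. No biological explanation was tested.

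The breaker library listed fewer sites than the other 3 libraries. Fewer sequenced tags may be a cause: at matched cDNA totals 35.3% of a cDNA's other sites were listed (95% interval 33.9 to 36.7), against 54.5%, 50.6% and 51.1% in the libraries of 5 days after pollination, mature green and 7 days after breaker. A smaller share of tags from these cDNAs may be another. For 1044 cDNAs listed in each library, the total at breaker was divided by the mean of the other libraries. The median of these ratios was 0.661, and 75.3% lay below 1. The same ratio was not taken for the other libraries, so it has no reference value, and cDNAs unlisted at breaker are left out. Tags spread more unevenly along each cDNA would also lower the listed share, and that was not tested. A difference between the stages also stays open, since stage and library are confounded.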
